A study of Homo sapiens with 6 samples.

How the data were processed

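Total RNA of MDA-MB-231 cells was sequenced after lentiviral transduction with PVT1 or with the empty vector, 3 libraries per group, and groups and replicate numbers were taken from the sample titles. The authors' deposited table gives, per gene and library, an estimated read count and an expression value, together with the group means of both. The submitters' processing notes name HISAT2 2.0.4, Bowtie2 2.2.5, RSEM 1.2.12 and the genome build GRCh38.p12, without saying what each was used for. The deposited estimated counts are not whole for 45.3 to 45.6% of values, which fits expected counts that share reads between similar transcripts. The unit of the deposited expression value is not given in the sources used here. The authors deposited it without a unit, and it was taken as FPKM, read counts scaled for transcript length and depth, because, over 6736 genes with at least 500 reads, the length that the count and the value imply had a median spread of 1.142% between libraries, and 86.9% of these genes stayed within 5%. The trimming, read length, strandedness and gene annotation are not given in the sources used here. Reads from overlapping genes on opposite strands may therefore be mixed, and reads of paralogs were divided by an estimate, which adds an error that the read counts do not show.

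The table held 17613 genes by Entrez number and symbol, of which 17428 were typed as mRNA and 135 as long noncoding RNA. Coordinates were taken from GENCODE 29 on GRCh38, matched by Entrez number for 17058 genes, with 555 not matched. The planned check of PVT1 in each library was not made, as PVT1 was not analysed here, and the planned fit without the PVT1 row is for that reason the same as the one reported. Group means in the table were not used. Library totals ran from 18314202 to 18644058 reads, so genes of a few CPM rest on few reads and are less precise. Counting intervals and floors cover counting error only, since no molecular identifiers are named.

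Estimated counts were rounded to whole numbers and tested in R 4.3.3 with edgeR 4.0.16. Genes were filtered with filterByExpr, which removed 3857 and left 13756, libraries were scaled by TMM (factors 0.9884 to 1.009), and the robust quasi-likelihood test compared the groups with no other term. P-values were adjusted by Benjamini-Hochberg and genes were called at 0.05. The common biological coefficient of variation was 0.0339. Levels are CPM with SD over 3 libraries. Before the data were examined, 26 gene lists were fixed from textbook knowledge, and 24 with at least 5 tested members were tested by camera of limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01, two-sided. The lists of mitochondrially encoded transcripts and of nuclear noncoding RNAs had 0 tested members and were not analysed here. The genes named were also set by a rule before the data were examined. It takes MYC, the 8 largest rises and 8 largest falls among called genes whose groups do not overlap and whose higher mean is at least 5 CPM, and up to 3 called members with the smallest adjusted p from each list. A gene that the rule takes is not reported here. Genes named outside it (TIMP3, ATF3, DDIT3, CHAC1, HSPA5, HSP90B1, CALR, XBP1, MANF, HYOU1, PPP1R15A and some in the closing section) were chosen after their values were seen.

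Replicates were compared by a chi-square of their counts, which was 1.92 to 3.98 per gene within groups and 11.75 to 17.6 between groups. Alternatives fixed before the data were examined were other scalings, other filters, the replicate number as a block, leaving out each library, DESeq2 1.42.0, limma-trend on log2 CPM and on log2(FPKM + 1) for genes of mean FPKM at least 1, a fit that is not robust, a 2-fold threshold, camera with an estimated correlation, and fry. A correction for GC content and transcript length (splines with 5 degrees of freedom, for 98.2% of tested genes), a test against a 1.2-fold change, scaling without the ribosomal protein genes and 4 further gene lists and the set of genes with a ZNF symbol were added after seeing the data.

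The gene test was tested on simulated counts for the same 13756 genes with 50 genes changed at each fold. It recovered 66% of genes changed 1.25-fold, 84% at 1.5-fold, 100% at 2-fold and 96% at 4-fold, and called 11 of 13556 unchanged genes. Far fewer genes were changed there than the 4329 called in the data. Its recovery and its number of false calls therefore do not carry over to the real comparison. In simulated counts, camera called a list of 40 genes shifted by 0.2 on the log2 scale and 0 of 20 random lists. The simulated genes were drawn independently, whereas the estimated correlation within the real lists reached 0.687. The simulation therefore cannot show how often camera wrongly calls lists of correlated genes.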

Results

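Gene expression was measured by RNA sequencing in MDA-MB-231, a basal-like human breast adenocarcinoma line with mesenchymal features. Cells transduced with a lentiviral vector carrying PVT1, a long noncoding RNA gene next to the MYC oncogene, were compared with cells given the empty vector. Each of the 2 groups had 3 libraries. The empty vector libraries 1 to 3 held 18476316, 18442378 and 18323866 estimated reads over 17613 genes, and the PVT1 libraries 1 to 3 held 18644058, 18335114 and 18314202, so depth was close to even. On log2 CPM (read counts scaled to a common library total), libraries correlated across genes at 0.9933 to 0.9944 within groups and 0.9869 to 0.9892 between groups, and the first principal component, with 47.9% of the variance, separated the groups. Every pair of libraries differed by more than counting noise, and none was treated as a duplicate.

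The comparison addressed which transcripts differ when PVT1 is over-expressed. PVT1 (chromosome 8, 127794533 to 128101253, GRCh38) was not analysed here, so the groups rest on the sample labels and the extent of its over-expression was not checked. MYC, the neighbouring gene at 127735434 to 127741434, had 176.2 ± 3.48 CPM (SD, n = 3) in empty vector cells and 170.1 ± 4.99 CPM (n = 3) in PVT1 cells, a log2 fold change of -0.05 (SE 0.04) that did not pass the test (edgeR adjusted p = 0.331). Of 20 tested genes around PVT1 at 8q24, 3 rose, 3 fell and 14 were not called, and the group as a whole was not called (camera adjusted p = 0.67). The ubiquitin ligase gene FBXO32 (123497889 to 123541206) rose by 0.62 on the log2 scale and the pseudokinase gene TRIB1 (125430321 to 125438405) by 0.56. FAM84B (126552442 to 126558393), whose locus overlaps the antisense gene PCAT1, changed by -0.45.

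In PVT1 cells, 34 of 40 genes of the hypoxia response and glycolysis, 61 of 78 cytosolic ribosomal protein genes, 16 of 25 TGF-beta targets and 20 of 36 extracellular matrix and protease genes rose, while 38 of 54 genes of G2 and mitosis and 18 of 26 YAP and TAZ targets fell. Each of these lists was called by camera with its preset correlation, and none with an estimated correlation (adjusted p = 0.42 for the ribosomal list, 0.17 for YAP and TAZ targets and 0.15 for the other lists). ANGPTL4, a secreted inhibitor of lipoprotein lipase, rose from 3.02 ± 0.51 to 14 ± 1.53 CPM (SD, n = 3 each), a log2 fold change of 2.21 (SE 0.13; edgeR adjusted p = 2.59e-13). IL11, a cytokine of the interleukin-6 family, fell from 201.6 ± 14.5 to 74.1 ± 3.23 CPM, a log2 fold change of -1.44 (SE 0.05; adjusted p = 4.72e-17). In all, 4329 of 13756 tested genes were called, 2199 higher and 2130 lower in PVT1 cells. Most differences were small: 3756 called genes changed by less than 1.5-fold, and 123 rose and 59 fell by at least 2-fold.

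Besides ANGPTL4 (Entrez gene 51129, chromosome 19, 8363289 to 8374373), the largest rises among genes of at least 5 CPM were in COL6A3, a chain of collagen VI, with a log2 fold change of 1.95 (SE 0.09), and HLA-DQB1, a chain of an MHC class II molecule, with 1.94 (SE 0.18). The HLA genes are close paralogs, and 5 of the 6 libraries had a fractional read estimate for HLA-DQB1, so its size is uncertain. AQP1, a water channel, rose by 1.81, TSC22D3, the glucocorticoid-induced leucine zipper, by 1.72, and SERPINA1, which encodes alpha-1 antitrypsin, by 1.71. NKX2-1, a homeobox factor of lung and thyroid, rose by 1.71, from 2.26 ± 0.33 to 7.41 ± 0.31 CPM, and PMEPA1 (Entrez gene 56937, chromosome 20, 57648392 to 57711536), a TGF-beta-induced inhibitor of SMAD signalling, by 1.69, from 30.94 ± 1.75 to 100.1 ± 6.19 CPM. Among genes of at least 5 CPM in empty vector cells, the largest fall was in DCLK1 (Entrez gene 9201, chromosome 13, 35768652 to 36131306), a doublecortin-like kinase. DCLK1 went from 12.87 ± 1.19 to 3.75 ± 0.49 CPM, a log2 fold change of -1.78 (SE 0.12). SP140, a nuclear body protein, changed by -1.53, IL11 (Entrez gene 3589, chromosome 19, 55364389 to 55370463) by -1.44, PDE1C, a calmodulin-dependent phosphodiesterase, by -1.42, SOCS2, a suppressor of cytokine signalling, by -1.37, the membrane mucin MUC4 by -1.33 and the cytokine IL34 by -1.32. SYN3, a synapsin gene, fell from 172.3 ± 7.48 to 69.28 ± 2.23 CPM, a log2 fold change of -1.31. Its locus (chromosome 22, 32512552 to 33058372) contains TIMP3 on the opposite strand, which itself had 856.1 CPM in empty vector cells and a log2 fold change of -0.39, and whether reads were counted by strand is not given in the sources used here. Genes on the opposite strand also overlap ANGPTL4, HLA-DQB1, TSC22D3, NKX2-1, PMEPA1, SP140 and SOCS2, and genes on the same strand overlap AQP1 and NKX2-1. Over all 85 genes named by rule, 28 were overlapped on the opposite strand and 10 on the same strand, and 24 had a fractional read estimate in at least 1 library, 17 of them in all 6 libraries, among these IL11, PDE1C and SYN3.

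**Figure D1:**
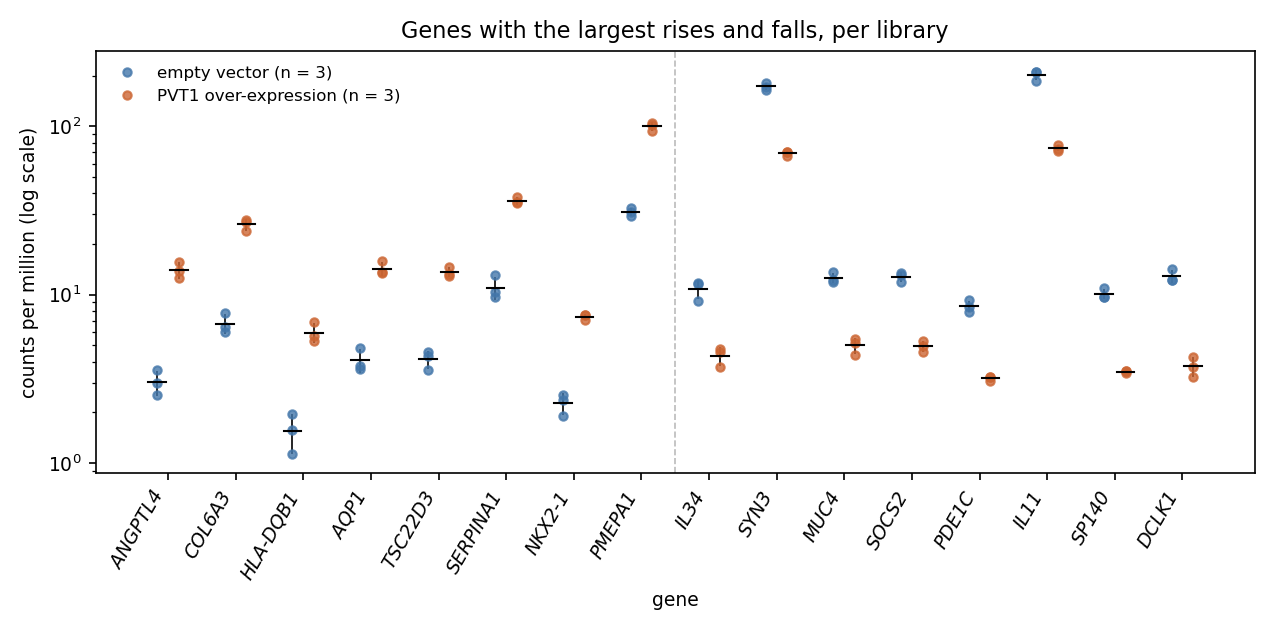
CPM (log axis) of the genes with the largest rises (left of the dashed line) and falls (right) in each of the 3 empty vector and 3 PVT1 libraries; points are libraries, horizontal lines group means and vertical lines SD. The rule took only genes whose groups do not overlap, such as ANGPTL4 with means of 3.02 and 14 CPM.

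Of 40 genes of the hypoxia response and glycolysis, 34 rose, 2 fell and 4 were not called, with a median log2 fold change of 0.41. The list was called as higher than other genes (camera adjusted p = 1.2e-15; adjusted p = 0.15 with an estimated correlation). NDRG1, a hypoxia-induced gene, rose from 80.09 ± 5.11 to 190 ± 9.51 CPM, which is 2.37-fold, and DDIT4, an inhibitor of mTORC1 signalling, from 99.54 ± 9.65 to 215.8 ± 5.33 CPM, a log2 fold change of 1.12 (SE 0.05). Rises were found both among the 20 members of glycolysis and glucose use, where 17 rose with a median of 0.30, and among the 20 other members, where 17 rose with a median of 0.67. Adjusted over the list alone, the counts for this list were again 34 and 2.

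Of 25 TGF-beta targets, 16 rose, 5 fell and 4 were not called (median 0.21; camera adjusted p = 0.00026; adjusted p = 0.15 with an estimated correlation). TGFBI, an extracellular matrix protein, rose by 0.97 and LTBP1, which binds latent TGF-beta, by 1.29 on the log2 scale. Of 36 extracellular matrix and protease genes, 20 rose, 5 fell and 11 were not called (median 0.24; camera adjusted p = 3e-04; adjusted p = 0.15 with an estimated correlation). The collagen genes COL6A1 and COL5A1 rose by 0.81 and 0.86. Among 19 mesenchymal genes, 9 rose, 4 fell and 6 were not called (median 0.26; camera adjusted p = 0.0059; adjusted p = 0.15 with an estimated correlation). The fibronectin gene FN1 rose by 0.71 and the calcium-binding protein gene S100A4 by 0.73. Of 21 epithelial genes, 5 rose, 7 fell and 9 were not called, and the list was not called (camera adjusted p = 0.67). SPINT1, a protease inhibitor, rose by 0.76 and the desmosomal gene PKP3 by 0.33, while the keratin gene KRT18 changed by -0.21. Adjusted over the list alone, 21 matrix genes rose and 6 fell, and the counts of the TGF-beta, mesenchymal and epithelial lists did not change.

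Of 54 genes of G2 and mitosis, 38 fell, 1 rose and 15 were not called (median -0.18; camera adjusted p = 1.5e-11; adjusted p = 0.15 with an estimated correlation). LBR, an inner nuclear membrane protein, changed by -0.37, the mitotic kinesin gene KIF20A by -0.32 and GTSE1, a G2 and S phase-expressed microtubule protein, by -0.32. Of 42 S phase genes, 12 rose, 1 fell and 29 were not called, and the list was not called (camera adjusted p = 0.089), although it was without empty vector library 1 (0.039) or without PVT1 library 1 (0.033). The histone chaperone gene NASP rose by 0.23 and the replicative helicase gene MCM6 by 0.20, and the chromatin remodeller gene HELLS changed by -0.21. Of 9 histone genes in the list of replication-dependent histones, 5 fell and 4 were not called (median -0.43; camera adjusted p = 0.0059; adjusted p = 0.15 with an estimated correlation). The falls included H1F0 (-0.43), a linker histone that is not in fact replication-dependent, HIST1H2BK (-0.57), with a fractional read estimate in all 6 libraries, and HIST1H1C (-0.62). Of 26 YAP and TAZ targets, 18 fell, 1 rose and 7 were not called (median -0.22; camera adjusted p = 1.9e-06; adjusted p = 0.17 with an estimated correlation). TGFB2, a TGF-beta ligand, changed by -0.46, the LIM protein gene AJUBA by -0.43 and the secreted glycoprotein gene FSTL1 by -0.35. Adjusted over the list alone, 38 G2 and mitosis genes fell and 2 rose, and the counts of the S phase, histone and YAP lists did not change.

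Of 78 cytosolic ribosomal protein genes, 61 rose, none fell and 17 were not called (median 0.17; camera adjusted p = 3.1e-12; adjusted p = 0.42 with an estimated correlation). RPL10A rose by 0.31, RPL13 by 0.39 and RPL4 by 0.27, and many genes of this family have processed pseudogenes that share reads with them. Of 58 MYC targets, 31 rose, 4 fell and 23 were not called (median 0.13; camera adjusted p = 4.6e-05; adjusted p = 0.33 with an estimated correlation). LDHA, the lactate dehydrogenase gene, rose from 2020 ± 34.4 to 2515 ± 38.8 CPM (0.32), and the ribosome biogenesis genes LAS1L (0.44) and RRP9 (0.42) rose as well. Of 48 nuclear genes of oxidative phosphorylation, 16 rose, 1 fell and 31 were not called (median 0.08; camera adjusted p = 0.00081; adjusted p = 0.42 with an estimated correlation). This list was no longer called after a correction for GC content and transcript length (0.21). The complex I subunit genes NDUFB7 and NDUFS3 each rose by 0.25 and SDHD, a subunit of complex II, by 0.17, with NDUFB7 not called after that correction (0.10, SE 0.05; adjusted p = 0.0944). Adjusted over the list alone, 67 ribosomal protein genes, 33 MYC targets and 18 oxidative phosphorylation genes rose, and 4 MYC targets and 2 oxidative phosphorylation genes fell.

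Of 45 interferon response genes, 21 rose, 5 fell and 19 were not called (median 0.21; camera adjusted p = 0.00093; adjusted p = 0.15 with an estimated correlation). The members with the smallest p-values went both ways: PSMB9, an immunoproteasome subunit, and the guanylate-binding protein gene GBP2 each rose by 0.77, and IFIT1, an antiviral protein induced by type I interferon, changed by -0.69. Of 32 NF-kB and inflammatory cytokine genes, 17 rose, 5 fell and 10 were not called (median 0.11; camera adjusted p = 0.0026; adjusted p = 0.15 with an estimated correlation). CSF2, encoding GM-CSF, rose by 1.21, and IL1B, encoding interleukin-1 beta, changed by -0.95, from 104.5 ± 4.2 to 54.19 ± 0.86 CPM. Of 36 immediate early and ERK feedback genes, 11 rose, 6 fell and 19 were not called. That list was not called (camera adjusted p = 0.056), but was without empty vector library 2 (0.024), empty vector library 3 (0.045) or PVT1 library 3 (0.047). The EGF receptor ligand gene EREG rose by 1.16, and the zinc finger factor genes KLF10 and EGR1 by 0.75 and 0.92. Adjusted over the list alone, 22 interferon genes, 18 NF-kB genes and 13 immediate early genes rose, and 7, 6 and 7 fell.

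Markers of other cell types were checked as well. Of 10 leukocyte markers, 5 rose, 1 fell and 4 were not called (camera adjusted p = 0.044; adjusted p = 0.43 with an estimated correlation). The leading genes were HLA-DRA (49.66 ± 4.08 to 132 ± 4.27 CPM), CD74 (429.3 ± 25.4 to 840.8 ± 11.4 CPM) and LAPTM5 (143.4 ± 7.85 to 215 ± 0.957 CPM), which were expressed in both groups. HLA-DRA and CD74 act in MHC class II antigen presentation, and LAPTM5 is a lysosomal membrane protein. Of 14 luminal breast markers, 6 rose, 1 fell and 7 were not called (camera adjusted p = 0.044; adjusted p = 0.39 with an estimated correlation). CA12, a carbonic anhydrase, rose from 23.5 ± 1.58 to 45.05 ± 1.48 CPM and AGR2, a secretory pathway protein, from 0.54 ± 0.15 to 2.84 ± 0.11 CPM. TFF1, a trefoil factor, had 0 reads in all 3 empty vector libraries and 16, 22 and 20 reads in the PVT1 libraries, at least 19.3-fold higher against a floor of 3 counts over the group. The leukocyte list lost its call without empty vector library 1 (0.064) or PVT1 library 2 (0.062), and the luminal list without PVT1 library 2 (0.077). After the GC and length correction neither list was called (0.08 for leukocyte and 0.096 for luminal markers); the leukocyte list was also not called with no low-count filter (0.061), nor the luminal list with a strict filter (0.096). Of 6 fibroblast and endothelial markers, 2 rose, 3 fell and 1 was not called, with the endothelial cadherin gene CDH5 at -1.63, the receptor gene PDGFRB at 0.54 and THY1 at -0.43, and the list was not called (camera adjusted p = 0.45). The counts adjusted over the list alone were the same for these 3 lists.

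**Figure D2:**
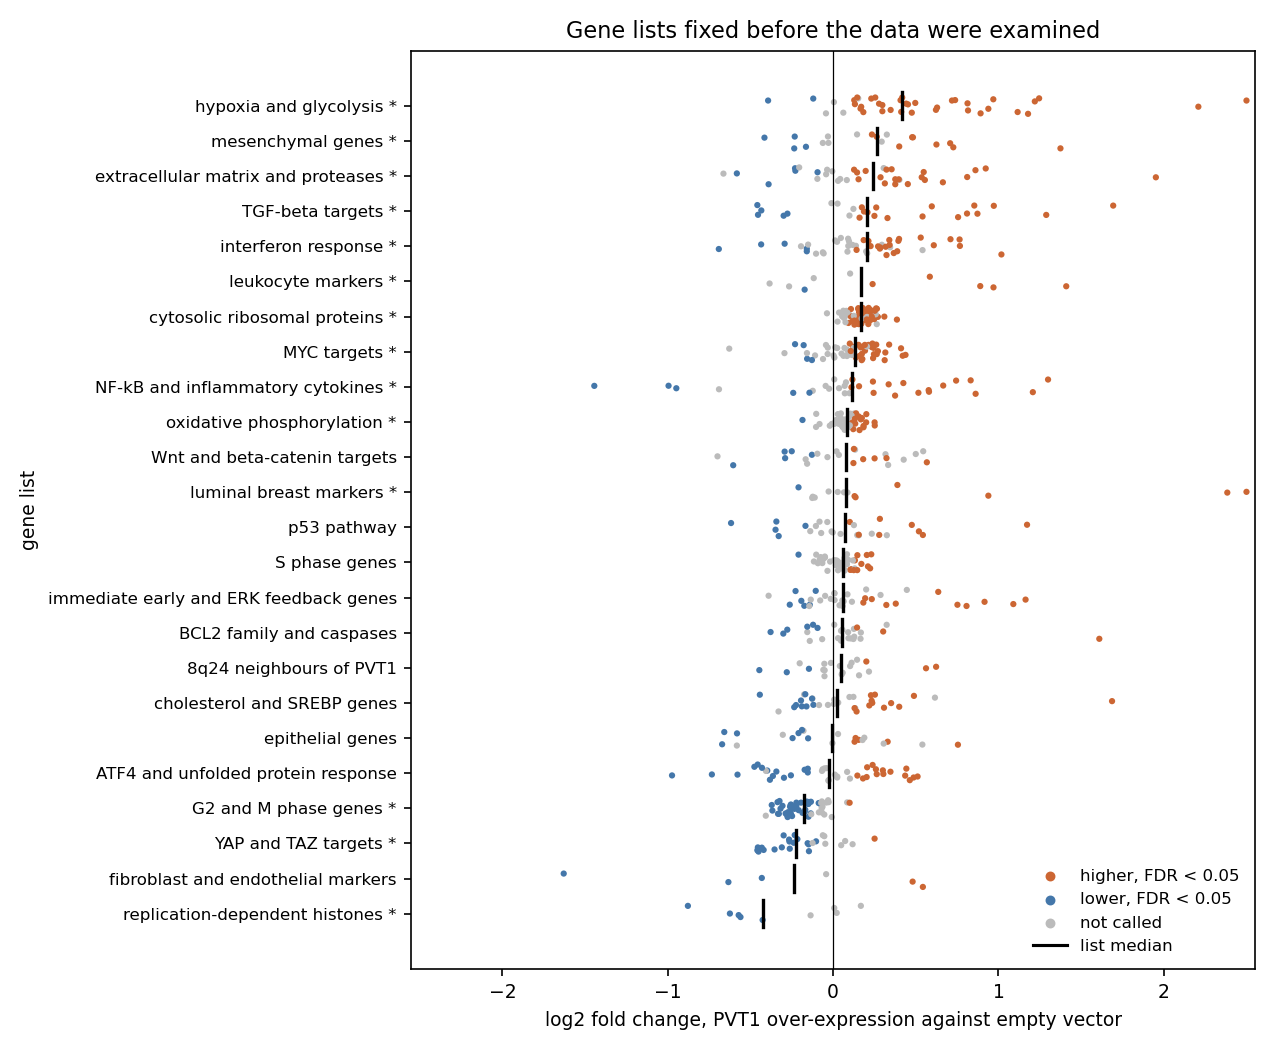
Log2 fold change (PVT1 over-expression against empty vector, 3 libraries each) of the tested members of each gene list, with members called higher in orange, called lower in blue and not called in grey; black lines are list medians, stars mark lists called by camera with its preset correlation, and 2 members beyond 2.5 are drawn at the edge. The hypoxia and glycolysis list has a median of 0.41 and the G2 and M phase list a median of -0.18.

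The other lists were not called. Of 26 p53 pathway genes, 8 rose, 5 fell and 13 were not called (camera adjusted p = 0.32). The cyclin-dependent kinase inhibitor gene CDKN1A rose from 36.58 ± 3.46 to 82.5 ± 2.27 CPM, a log2 fold change of 1.17, while the kinase gene PLK2 changed by -0.62 and CCNG1 by -0.34. Of 42 ATF4 and unfolded protein response genes, 15 rose, 15 fell and 12 were not called (camera adjusted p = 0.77). The genes of asparagine and serine synthesis ASNS and PSAT1 changed by -0.73 and -0.48, and the glycyl-tRNA synthetase gene GARS by -0.34. When the list was split after its values were seen, the parts moved in opposite directions. All 15 genes that fell were among 26 members taken as amino acid response genes, of which 3 rose. That part also holds genes shared with the unfolded protein response, such as DDIT3 (-0.255) and CHAC1 (-0.398), which fell, and ATF3 (0.464), which rose. None of the remaining members fell. Among them HSPA5 and HSP90B1 each rose by 0.30 and CALR by 0.24, while XBP1, MANF, HYOU1 and PPP1R15A were not called. Of 34 cholesterol and SREBP genes, 12 rose, 9 fell and 13 were not called (camera adjusted p = 0.36), with ABCA1, a cholesterol exporter, up by 1.69, the regulator gene SREBF1 up by 0.40 and the desaturase gene SCD up by 0.49. Of 24 Wnt and beta-catenin targets, 6 rose, 5 fell and 13 were not called (camera adjusted p = 0.48). PORCN, which acylates Wnt proteins, rose by 0.57 and the beta-catenin gene CTNNB1 by 0.25, while DKK1, a secreted Wnt inhibitor, changed by -0.29. Of 26 BCL2 family and caspase genes, 3 rose, 6 fell and 17 were not called (camera adjusted p = 0.51), and although more fell than rose the median was 0.05. BMF, a pro-apoptotic BH3-only gene, rose from 2.55 ± 0.44 to 7.81 ± 0.54 CPM and BID by 0.30 on the log2 scale, and BOK changed by -0.28. Adjusted over the list alone, 13 cholesterol genes rose and 11 fell, 9 Wnt targets rose and 7 fell, and 16 ATF4 genes rose and 15 fell, while the counts of the p53, BCL2 and 8q24 lists did not change.

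Gene calls came from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment at 0.05. The libraries of the groups did not overlap for 43.3% of all tested genes, where chance gives 10% for 3 against 3. Of 24 lists tested by camera, 14 were called with the preset correlation of 0.01 (11 higher and 3 lower); with an estimated correlation 0 were called, 8 having an unadjusted p under 0.05, while fry, which tests each list without comparing it with other genes, called 19. The labels do not say that the 3 libraries of a group came from separate cultures or transductions, so the p-values measure only the spread between these libraries, which may be technical.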

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

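The GC and length correction, the test against a 1.2-fold change and the scaling without ribosomal protein genes were chosen after seeing the data. The 4329 called genes became 4339 with DESeq2 size factors, 4353 with library totals, 4478 with no filter, 3799 with a strict filter, 4210 without robust fitting, 4294 with limma-trend on CPM, 3726 on FPKM, 3232 with DESeq2 (534 genes without an adjusted p) and 4981 after the GC and length correction, and every gene called both there and in the reported test had the same direction. The balance of 2199 higher and 2130 lower turned to 1845 and 2508 with library totals, 1613 and 2113 on FPKM and 2423 and 2558 after the correction. Leaving out each library gave 3469 to 4447. The count depended on the size asked for: at least 2-fold left 182 genes (123 higher, 59 lower), and the test against a 1.2-fold change left 755 (423 higher, 332 lower). With an estimated correlation, camera called 0 lists (0 higher, 0 lower), 8 having an unadjusted p under 0.05, against 14 reported and 19 by fry. Correlation between members cannot be the whole cause. The estimate was below the preset 0.01 for the mesenchymal (0), TGF-beta (0.003), NF-kB (-0.014) and histone (-0.099) lists. Their unadjusted camera p still rose, from 6.4e-05 to 0.013 for TGF-beta targets and from 0.003 to 0.037 for histones. For ribosomal proteins (0.687) and oxidative phosphorylation (0.235) the estimate was far above the preset. The reference for the p-value also differs between these forms of camera. With an estimated correlation it has only the few degrees of freedom that 6 libraries leave. With a preset correlation it has nearly as many as there are genes. How far this alone raised each p was not tested. Over 13 scalings, filters, corrections, the block and left-out libraries, 11 of the 14 lists were called each time they could be tested. The exceptions were luminal markers (adjusted p 0.026 to 0.096, called in 9 of 13), leukocyte markers (0.002 to 0.11, called in 8) and oxidative phosphorylation (2.3e-05 to 0.21, called in 12). Without empty vector library 1 the leukocyte list had 0.064, and without PVT1 library 2 the leukocyte and luminal lists had 0.062 and 0.077. The S phase list (0.033 to 0.26) was called in 3 of 13, among them after the GC and length correction (0.045) and without empty vector library 1 (0.039) or PVT1 library 1 (0.033). The immediate early list (0.024 to 0.21) was called in 4, with no filter (0.039) and without empty vector library 2 (0.024), empty vector library 3 (0.045) or PVT1 library 3 (0.047). Of 85 named genes, 0 lost the call or changed sign when a library was left out, and under the other settings NDUFB7 alone lost it. At these depths, genes with few reads, such as TFF1, support only bounds.

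Fitting the replicate number as a block called 4479 genes, 2280 higher and 2199 lower, and left the luminal (0.054) and leukocyte (0.11) lists uncalled. The numbers did not pair the libraries: the deviations of same-numbered libraries from their group means correlated at 0.053, -0.003 and -0.007, and 2 of the 6 libraries correlated best with their own number.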

Other observations

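The added gene lists and the tests of culture density, of amino acid depletion and of luminal cells were chosen only after the results they measure were seen, except that FOXO targets were listed before their values were looked at. The rises of HLA-DRA, HLA-DQB1 and CD74 prompted a look at other MHC class II genes, of which 10 of 11 tested rose and 1 was not called, with a median log2 fold change of 1.01 (camera p = 1e-08; p = 0.017 with an estimated correlation, both unadjusted). HLA-DRB1 rose from 38.82 ± 4.16 to 92.72 ± 2.73 CPM (SD, n = 3 each; edgeR adjusted p = 1.28e-14), HLA-DPA1 from 21.63 ± 2.16 to 52.95 ± 0.61 CPM, and CIITA, the class II transactivator gene, by 0.30 on the log2 scale. Of 14 MHC class I and peptide loading genes, leaving out TAP1, PSMB8 and PSMB9 of the interferon list, 12 rose and 2 were not called, with a median of 0.43 (camera p = 9.1e-10; p = 0.022 with an estimated correlation). As the lists were made after seeing the data, these p-values are not independent evidence. HLA-B rose by 0.90, the immunoproteasome gene PSMB10 by 0.99 and the aminopeptidase gene ERAP1 by 0.59, while NLRC5, a regulator of class I genes, was not called (0.07). The HLA genes are paralogs with reads divided by an estimate. HLA-DRA and CD74 are also in the leukocyte list, where LAPTM5 (143.4 ± 7.85 to 215 ± 0.957 CPM), CSF1R (5.77 ± 0.18 to 10.7 ± 1.02 CPM) and CD68 (199.7 ± 13.5 to 235.6 ± 3.51 CPM) rose as well. In that list ITGB2 fell (49.39 ± 3.18 to 43.83 ± 2.1 CPM), and PTPRC (0.99 ± 0.25 and 0.91 ± 0.03 CPM), CD14 (5.48 ± 0.7 and 4.56 ± 0.51 CPM), LYZ (1.83 ± 0.2 and 1.4 ± 0.17 CPM) and CORO1A (3.99 ± 0.78 and 4.29 ± 0.54 CPM) were not called.

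A few genes were near absent in a group, with at most 3 reads over its libraries and at least 20 over those of the other. ALDH1A1, a retinaldehyde dehydrogenase gene, had 0 reads in each empty vector library and 23, 21 and 25 in the PVT1 libraries, at least 23-fold higher against a floor of 3 counts over the group. SERPINA3, encoding alpha-1 antichymotrypsin, had 3 reads in all against 80 (ratio 26.6, 95% counting interval 8.79 to 132), CHI3L2 2 against 31 (15.5, 3.94 to 134), TPPP3 3 against 32 (10.7, 3.33 to 54.4) and ENTPD2 3 against 27 (8.99, 2.77 to 46.3). MRC1, the macrophage mannose receptor gene, had 20 reads in empty vector cells against 3 in PVT1 cells (0.15, 0.0285 to 0.505). Beside TFF1, AGR2, SPDEF and MUC4, whose values had been seen, 5 mucin genes were tested, of which 2 rose and 3 were not called, and as a list they were not called (camera p = 0.087; p = 0.27 with an estimated correlation). MUC5B rose from 18.69 ± 3.98 to 59.5 ± 11.6 CPM and MUC1 from 13.44 ± 1.56 to 25.98 ± 0.66 CPM. Of 462 genes with a ZNF symbol, many of which encode KRAB zinc finger repressors, 94 fell and 13 rose, with a median of -0.10 (camera p = 2.9e-05; p = 0.043 with an estimated correlation) and of -0.08 after the GC and length correction. Some blocks of neighbouring genes on chromosome 19 were also lower, with a median of -0.141 from 20776304 to 33302564. Whether the fall of the ZNF genes followed gene family or chromosome region was not tested.

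Many genes were called with small folds. A trend with GC content or transcript length as the whole cause is argued against, since 4981 genes were called after it was removed. Copy number differences between the cell pools, if they were the cause, would shift neighbouring genes together. Of 328 blocks of 40 neighbouring genes, 4 had a median beyond the 0.14 that gene shuffles allowed, and these held 1.65% of called genes. The largest shift, 0.19, was on chromosome 6 from 31969810 to 33317942, which holds MHC genes. The others were falls, of -0.154 on chromosome 1 (205086142 to 211316385) and -0.141 on chromosome 19 (20776304 to 33302564, and 42198598 to 44134816). Whole-block shifts beyond 0.14 are thus argued against as the main cause. Smaller shifts, or shifts over part of a block, would not be seen and remain open. The 6 libraries allow 10 splits, too few for a share under 0.05: 1 split, the real one, gave as many genes (4329 called, the highest other 0 by edgeR, with up to 398 at an unadjusted p under 0.05), and 1 gave as many called lists (14, the highest other 7). An effect of PVT1, a difference between the transduced cell pools and a difference in handling remain open, as each follows the groups.

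Of the hypoxia and glycolysis list 34 of 40 genes rose, while 38 of 54 G2 and mitosis genes and 18 of 26 YAP and TAZ targets fell (adjusted p = 0.15, 0.15 and 0.17 with an estimated correlation). GC content or transcript length is argued against, as at least 95.5% of each of the 3 list medians remained after the correction. Amino acid depletion of the medium in the PVT1 dishes would raise the amino acid genes of the ATF4 list, but their median was -0.21 (95% bootstrap interval over 26 genes, which are not independent, -0.38 to -0.05), with 15 lower and 3 higher. Lower oxygen or denser culture in the PVT1 dishes cannot be told apart from the vector, since the labels give neither; that 85% of the 20 hypoxia list members outside glycolysis rose restates the pattern and does not test it. A response to PVT1 stays open in the same way, and cell counts at harvest would help to decide.

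RNA of luminal breast cells may account for the reads of TFF1, which had none in empty vector cells, and for the rise of AGR2 from 0.54 ± 0.15 to 2.84 ± 0.11 CPM. Of 14 luminal markers tested, 12 had at least 1 CPM in empty vector cells and 5 are also in other lists, and the most abundant, KRT8 (490.5 to 539 CPM), KRT18 (374.4 to 323.9 CPM) and KRT19 (258.4 to 282.8 CPM), have levels that would hide a small share of luminal cells. A first form of the test over the 12 other markers, of which 33.3% rose with a median of 0.05, was set aside for that reason. Of 3 other luminal markers whose level in empty vector cells was below that of TFF1 in PVT1 cells, 1 had more reads in PVT1 cells, PGR with 0 against 7 (exact binomial p = 0.0156, two-sided), while FOXA1 had 17 against 11 and TFF3 1 against 1. With so few reads, luminal RNA and induction in the cells themselves cannot be told apart.

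TSC22D3, CDKN1A, BMF and FBXO32, which rose by 1.72, 1.17, 1.61 and 0.62 on the log2 scale, are all known targets of FOXO factors, and higher FOXO activity in PVT1 cells was tested as a hypothesis on other FOXO targets. Of 22 such genes, 10 rose, 3 fell and 9 were not called, with a median of 0.16 (camera p = 0.0055; p = 0.22 with an estimated correlation). TXNIP rose by 0.63, but PINK1 and CITED2 changed by -0.53 and -0.37. Fewer than the majority set beforehand rose, so the hypothesis may hold for part of these genes but is not settled.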
